A study of Mus musculus with 6 samples.

How the data were processed

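RNA from 6 cultured mouse mammary cell lines of the FVB/N strain was sequenced. The labels name 3 of the lines EIC and 3 of them 16IC, and all were kept in doxycycline at 10 ug/mL in medium with 10% serum, EGF, insulin and pituitary extract. From background on the study, and not from the labels, doxycycline switches on wild-type ErbB2 in EIC and the HER2 splice form that lacks exon 16 in 16IC. The species of the transgenes is not given in the sources used here. RNA was taken with a column kit and libraries were made with the NEBNext Ultra II kit. Replicate numbers follow the order of the deposited samples and pair no line of one group with a line of the other.

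Per the submitters' processing notes, the tools named were Trimmomatic, STAR, HTSeq, edgeR and limma, and the genome builds named were GRCm38 and mm10. The role and version of each tool, the settings, the strandedness and the annotation release are not given in the sources used here. The deposited table gives the authors' read count per gene and library as whole numbers. It also gives a normalised signal that the authors made by dividing each count by 1 size factor per library, with the mean of that signal per group. The FPKM columns were made by the authors from the count, the gene length in the table and a library size between 15473035 and 18086973, which differs from the column totals. The authors' comparison of the groups is held as a log2 fold change, a p-value and an adjusted p-value per gene. Their size factors equalled those that DESeq2 computes from the same counts. Their log2 fold change lay within 0.01 of that from a DESeq2 run on the counts in 99.98% of genes, although the tool behind their comparison is not stated.

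Computations started from the deposited counts of 23449 genes. Library totals ranged from 15621563 to 17468498 counts. Genes with too few counts were removed with edgeR's filterByExpr by group, with its minimum count of 10, which left 13698 genes. Library sizes were scaled with TMM factors, and 16IC was compared with EIC by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjusted p under 0.05. No block was fitted, since nothing in the labels pairs or batches the lines. Levels are given as CPM, the count per megacount of the TMM-scaled library size, with the mean ± SD over the 3 lines of a group. Fold changes are 16IC over EIC, so that a positive log2 value is higher in 16IC, and SE is the standard error of the fitted value.

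In total 26 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes, except where a later choice is stated. Each list with at least 5 tested members, 23 in all, was tested with camera (limma 3.58.1) on voom weights. Camera's preset inter-gene correlation of 0.01 was used, with Benjamini-Hochberg adjustment over the lists. The lists cover ERBB receptors and ligands, ENPP1 and extracellular nucleotide handling, the cGAS-STING pathway, interferon-stimulated genes, MHC class I, MHC class II, chemokines and cytokines, and immune checkpoint ligands. They also cover MAPK output, PI3K-AKT and FOXO targets, TGF-beta targets, Wnt targets, p53 targets, proliferation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis and the unfolded protein response. The remaining lists hold markers of luminal, basal, mesenchymal, fibroblast, endothelial, leukocyte and adipocyte cells, and sex-linked genes. The level of a list in a line is the median over its members of log2 CPM after each gene was centred on its mean over the 6 lines.

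Genes were named by 1 rule. Enpp1 and Erbb2 were always named. The 12 largest rises and the 12 largest falls were taken by fitted log2 fold change among genes under the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out predicted or unnamed models. From each list up to 4 members with the smallest p were open to naming. A gene outside the rule is said to be chosen after its values were seen. Where a group had 0 counts in all 3 lines, the fold was computed against a floor of 3 counts over the group and is a lower bound. Where a group had 1 to 3 counts and a fold is printed, it is the ratio of the groups' summed counts, scaled for library size, with its exact 95% binomial counting interval. Other genes with so few counts are named without a fold. Such intervals and floors cover counting error only, since the libraries hold no molecular identifiers.

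Alternatives were DESeq2 size factors and upper-quartile factors in the edgeR fit, no filter on low counts, a filter of at least 1 CPM in 3 libraries, leaving out each line in turn, the robust quasi-likelihood fit, limma-voom, DESeq2 1.42.0, a test against a fold of 1.5, and adjusted p thresholds of 0.01 and 0.1. For the lists they also included camera with an estimated correlation, and fry. Averaging 16IC 1 and 16IC 2 to 1 sample was added after seeing the data. The gene tests were also tested on simulated data. In 5 simulations with 200 changed genes of 13698, edgeR recovered 30.2% of those changed 4-fold and 81% of those changed 16-fold, with 5.44% false calls. On the same simulated counts voom recovered 27% and 78.2%, with 6.41% false, and DESeq2 recovered 71.4% and 94.8%, with 33.8% false. These counts were drawn gene by gene with the dispersions that edgeR estimated, so the false shares hold for that setting only.

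Some named genes overlap another gene in the table or have close relatives, so that reads can be shared between them or lost. This holds, among others, for Erbb2 with Mien1, Ifi203 with Mndal, Tapbpl with Vamp1, Wnt5b with Fbxl14, Esrp2 with Nfatc3, Jun with Junos, Cdc20 with Elovl1 and Cxcl16 with Zmynd15, and for the families of Ifit2, Raet1e, Csf2rb and the H2 genes. The table has a mouse Erbb2 gene only, so reads of a transgene of another species would have no gene of their own in it. Whether such reads were lost or counted under Erbb2 is not known.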

Results

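Messenger RNA levels were measured in 6 mouse mammary cell lines, 3 named EIC and 3 named 16IC, all in doxycycline. From background on the study, and not from the labels of the samples, EIC stands for inducible wild-type ErbB2, the receptor tyrosine kinase also called HER2. By the same background 16IC stands for the HER2 splice form without exon 16. Total counts were 17468498, 16742109 and 17268276 in EIC 1 to 3 and 15669164, 16091846 and 15621563 in 16IC 1 to 3. Mitochondrial genes, looked at after the values were seen, took 1.5, 0.93 and 1.4% of the counts in EIC 1 to 3 and 2.0, 2.2 and 3.4% in 16IC 1 to 3, groups that did not overlap, as chance gives in 10% of cases. Nothing in the labels says which animals or cultures the lines came from, so each p-value measures the spread between these 6 samples.

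The lines of a group were not equally alike. Spearman correlation of log2 CPM across the tested genes, which are not independent replicates, was 0.989 between 16IC 1 and 16IC 2 and 0.979 between EIC 1 and EIC 3. EIC 2 reached 0.925 with EIC 1 and 0.917 with EIC 3. The line 16IC 3 reached 0.874 with 16IC 1 and 0.880 with 16IC 2, within the 0.841 to 0.885 found between lines of different groups. The first principal component held 54.4% of the variance and placed 16IC 3 at 9.45, between 16IC 1 and 16IC 2 at 110.0 and 102 and the EIC lines at -82.4 to -64.9. The second component, with 21.1%, set 16IC 3 apart at -111, and the third, with 18.5%, set EIC 2 apart at -93.7. EIC 2 is also the line whose title has NT where the other titles have a number, and the labels do not say what NT means. The mean distance between lines of a group, as 1 minus the correlation, was 0.0726, and it was 0.0460 without 16IC 3.

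**Figure D1:**
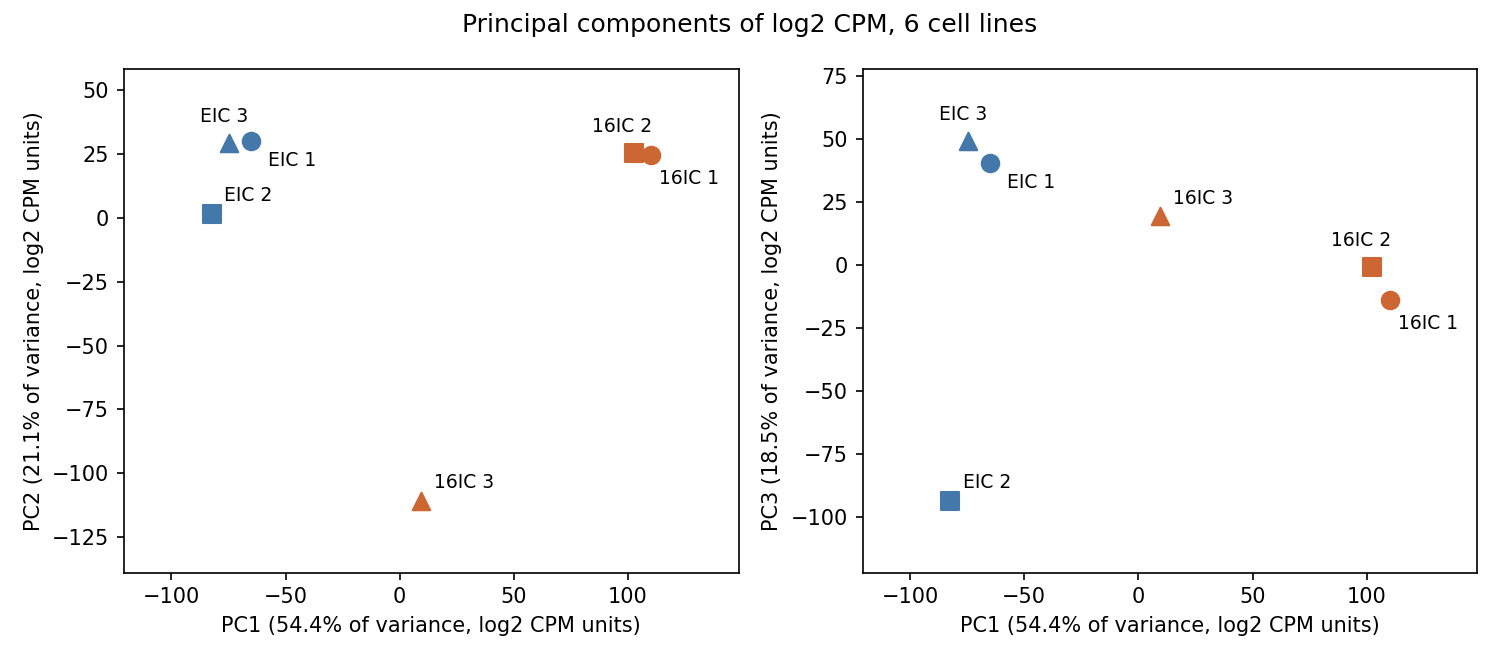
Positions of the 6 cell lines on the first 3 principal components of log2 CPM, with EIC in blue, 16IC in orange and 1 symbol per line. On the first component (54.4% of variance) 16IC 3 sits at 9.45, between the other 16IC lines (102 and 110.0) and the EIC lines (-82.4 to -64.9).

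The comparison of 16IC with EIC asks, on that background, how cells with the shorter HER2 form differ in expression from cells with the full-length receptor. As no line was kept without doxycycline, an effect of the receptor form cannot be told apart from other differences between the lines. The 16IC lines expressed the epithelial regulators Elf5 and Esrp1, which were nearly silent in the EIC lines, with lower levels in 16IC 3 than in the other 16IC lines. The EIC lines expressed the cytokine-receptor gene Csf2rb and the matrix genes Emilin2 and Efemp1, which were nearly silent in 16IC. As sets under camera's preset correlation, genes of interferon response and of the unfolded protein response were lower in 16IC, and genes of cholesterol synthesis were higher. With an estimated correlation camera called 0 of the 23 lists (adjusted p = 0.646, 0.475 and 0.646 for these 3), while fry called 3 lists, of these 3 the unfolded protein response alone.

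Of 13698 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 335, of which 171 were higher and 164 lower in 16IC. The smallest adjusted p was 0.0143, and 3110 genes had an unadjusted p under 0.05. All 335 had groups that did not overlap, as did 31.4% of tested genes, where chance gives 10%. The number called depended on single lines. The edgeR test called 0 genes without EIC 1, EIC 3 or 16IC 2, with 2627, 2341 and 2251 genes at an unadjusted p under 0.05. It called 5 without 16IC 1, 282 without EIC 2 and 1913 without 16IC 3. With 16IC 1 and 16IC 2 averaged to 1 sample edgeR called 0, with 2257 at an unadjusted p under 0.05, and voom and DESeq2 were not run. That was tried after seeing the data, as these 2 lines are the most alike pair and the labels do not say whether they come from separate animals. With all 6 lines limma-voom called 287 and DESeq2 called 2032. The authors' deposited table has 2024 genes at an adjusted p under 0.05, 1090 higher and 934 lower, and all 335 of the edgeR calls are among them with the same direction.

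The largest rises included regulators of epithelial cells. Map3k21, a kinase of the mixed-lineage family, had 32.8 ± 5.63 CPM in 16IC and 1 count over the EIC lines, a ratio of 1644 (95% counting interval 295 to 64958). Slc38a1, a glutamine transporter, had 49.4 ± 31.5 CPM against 2 EIC counts, a ratio of 1244 (95% counting interval 344 to 10279). Elf5, a transcription factor of the milk-secreting lineage, had 35.8 ± 30.5 CPM against 3 EIC counts, a ratio of 610.2 (95% counting interval 208 to 2962). Esrp1, which directs epithelial splicing, rose from 0.557 ± 0.435 CPM to 149 ± 107 CPM (log2 fold change 8.05, SE 1.22, edgeR adjusted p = 0.0391). The membrane protease gene Tmprss2 rose from a mean of 0.174 to 67.4 ± 54.3 CPM, and the growth factor gene Pdgfb from 0.117 to 34.0 ± 27.9 CPM. Both were lowest in 16IC 3 among the 16IC lines, at 4.93 and 4.02 CPM. Cds1, Nlrp10, Unc5cl, Shank2, Plekhs1 and Sel1l3 completed the 12 largest rises, with 16IC means of 7.99 to 32.6 CPM and EIC means of at most 0.142 CPM. Of these genes Unc5cl was highest in 16IC 3 (22.1 CPM). The others were lowest there among the 16IC lines, at 1.75 to 8.89 CPM. The largest falls included Csf2rb, a shared subunit of cytokine receptors, which had 10.2 ± 8.01 CPM in EIC and 0 counts in 16IC and was at least 164-fold lower. Emilin2, a matrix glycoprotein gene, fell from 357 ± 211 CPM to 0.792 ± 0.621 CPM (log2 fold change -8.81, SE 0.97, edgeR adjusted p = 0.0285). Efemp1, which encodes another matrix protein, fell from 364 ± 259 CPM to 0.838 ± 1.25 CPM. Chst1, a sulfotransferase gene, fell from 114 ± 9.39 CPM to a mean of 0.443 CPM, and the sarcoglycan gene Sgce from 64.8 ± 20.6 CPM to a mean of 0.293 CPM. Camk1d, a calcium-dependent kinase gene, had 31.5 ± 7.68 CPM in EIC against 2 counts in 16IC, a ratio of 759 (95% counting interval 209.8 to 6273). F13a1, Syt7, Medag, Meis1, Fam20c and Fbxl16 completed the 12 largest falls, with EIC means of 6.24 to 65.2 CPM. None of the called genes named here or later kept its edgeR call without EIC 1, EIC 3 or 16IC 2, where their adjusted p ranged over 0.0942 to 0.169, 0.142 to 0.185 and 0.110 to 0.194. Of these 48 genes, all were called without 16IC 3, 24 without EIC 2 and 3 without 16IC 1. Limma-voom called 33 of them, and of those named in this paragraph not Elf5, Esrp1, Tmprss2, Pdgfb, Cds1, Nlrp10, Shank2, Plekhs1, Sel1l3, F13a1, Syt7 or Fam20c (adjusted p = 0.0667 to 0.241). The robust fit did not call Tmprss2 (adjusted p = 0.0512) or Csf2rb (0.0508).

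The series concerns ENPP1, an ectoenzyme that cleaves ATP and the STING activator cGAMP outside the cell. Enpp1 (ENSMUSG00000037370, chromosome 10, 24637914 to 24712159 on mm10) had 38.9, 61.1 and 1.82 CPM in 16IC 1 to 3 and 0.627, 0.0601 and 3.17 CPM in EIC 1 to 3. The means were 33.9 ± 29.96 CPM and 1.29 ± 1.66 CPM (SD, n = 3), and 16IC 3 lay below EIC 3. The log2 fold change was 4.72 (SE 1.62), which edgeR's quasi-likelihood test did not call (adjusted p = 0.157). Without 16IC 3 the log2 fold change was 5.28 and edgeR called it (adjusted p = 0.0471), and across all alternatives the adjusted p ran from 0.00388 with DESeq2 to 0.342 without 16IC 2. In the authors' deposited table its log2 fold change is 4.69, with an adjusted p of 0.00388. Erbb2 (ENSMUSG00000062312, chromosome 11, 98412470 to 98437716) had 132 ± 26.3 CPM in 16IC and 78.2 ± 9.75 CPM in EIC (SD, n = 3), and all 3 16IC lines lay above all 3 EIC lines. Its log2 fold change was 0.76 (SE 0.21, edgeR adjusted p = 0.108), and without 16IC 3 it was 0.91 and called (adjusted p = 0.0259), with a range over alternatives up to 0.305. Whether transgene reads were counted under Erbb2 is not known. These values therefore cannot separate the mouse gene from the transgenes, and are no direct check of them. Of 20 tested members of the ENPP1 and extracellular nucleotide list edgeR called 1, the ATP-gated channel gene P2rx7, which rose from 11.3 ± 1.13 CPM to 46.2 ± 12.7 CPM (edgeR adjusted p = 0.0360). This call was lost without EIC 1, EIC 3, 16IC 1 or 16IC 2 (adjusted p = 0.121 to 0.157). Adjusted over the list alone, 3 were called, and camera did not call the list (adjusted p = 0.311). Enpp2, which encodes autotaxin, had 65.5 ± 68.5 CPM in EIC and 2.62 ± 2.29 CPM in 16IC without passing the edgeR test (adjusted p = 0.0899). Its EIC lines ranged widely, with 45.0, 9.62 and 142 CPM in EIC 1 to 3.

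Interferon-stimulated genes were lower in 16IC as a set under camera's preset correlation only. Of 49 tested members, 46 had a negative log2 fold change, with a median of -1.01, and camera called the list (adjusted p = 6.29e-10). With an estimated correlation camera did not call it (adjusted p = 0.646), nor did it call any of the 23 lists, and fry did not call it (adjusted p = 0.175). The gene-wise edgeR test called 1 member, Ifit2, and adjusted over the list alone it called 8, all lower. Ifit2, which binds viral RNA, fell from 55.0 ± 11.6 CPM to 20.4 ± 3.50 CPM (edgeR adjusted p = 0.0467), and it lost this call without EIC 1, EIC 3, 16IC 1 or 16IC 2 (adjusted p = 0.163 to 0.188). It also lost it with upper-quartile factors (adjusted p = 0.0512), with no filter on low counts (0.0536) and with 16IC 1 and 16IC 2 averaged (0.182). Usp18, a brake on interferon receptor signalling, had 98.9 CPM in EIC and 28.1 CPM in 16IC and stayed above the threshold in edgeR (adjusted p = 0.0526), as did Mx1 with 5.41 and 0.427 CPM (adjusted p = 0.0708). The difference was smaller in 16IC 3. Against every EIC line, 42 members were lower in 16IC 1, 44 in 16IC 2 and 22 in 16IC 3, where chance gives 25% for a single gene. The members are not independent, and the same share over all tested genes was not computed, so these counts are descriptive. The list median was -1.67 without 16IC 3 and -0.70 without 16IC 2, and camera called the list whichever line was left out (adjusted p 7.87e-15 to 2.47e-07).

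Antigen presentation, DNA sensing, chemokine and checkpoint lists were also examined. In MHC class I antigen presentation 22 of 23 tested members had a negative log2 fold change (median -0.59) and camera called the list (adjusted p = 0.0200). It did not with an estimated correlation (adjusted p = 0.676), nor without EIC 2, 16IC 1 or 16IC 2 (adjusted p = 0.430, 0.122 and 0.169). The level of 16IC 3 was 0.71, above EIC 1 and EIC 3 (-0.07 and -0.04) and below EIC 2 (1.15), while 16IC 1 and 16IC 2 were at -0.90 and -0.77. Its 1 edgeR call, also the 1 call adjusted over the list alone, went the other way: Tapbpl, which edits peptides on class I molecules, rose from 12.97 ± 3.63 CPM to 37.7 ± 4.39 CPM (edgeR adjusted p = 0.0492). In the cGAS-STING list edgeR called 2 of 19 members, and 3 adjusted over the list alone, while camera called no set change (adjusted p = 0.686). Its median was 0.07 and its mean -0.21, the sign of the test. The kinase gene Ikbke rose from 23.8 ± 3.19 CPM to 55.1 ± 7.998 CPM (edgeR adjusted p = 0.0461), and the DNA-sensor family gene Ifi203 fell from 86.0 ± 10.7 CPM to 19.9 ± 9.23 CPM (edgeR adjusted p = 0.0455). Of 32 chemokine and cytokine genes edgeR called Ptges alone, and 8 were called adjusted over the list alone, while camera gave an adjusted p of 0.219, and called the list lower without EIC 2 (adjusted p = 0.0456). Ptges, a prostaglandin E synthase gene, fell from 301 ± 220.2 CPM to 2.44 ± 2.88 CPM (edgeR adjusted p = 0.0461). Cxcl16 had 10.3 CPM in EIC and 149 CPM in 16IC and narrowly missed the threshold in edgeR (adjusted p = 0.0501), as did Cxcl10 with 3.74 and 0.745 CPM (adjusted p = 0.0518). Among 18 checkpoint ligands edgeR called 2, and 4 adjusted over the list alone, with a camera adjusted p of 0.450. Cd200, an inhibitory ligand for myeloid cells, rose from 36.5 ± 7.93 CPM to 187 ± 51.5 CPM (edgeR adjusted p = 0.0360). Raet1e, a ligand of the NKG2D receptor, fell from 10.9 ± 2.33 CPM to a mean of 0.104 CPM (edgeR adjusted p = 0.0360). Of the MHC class II list 3 members were tested and edgeR, voom and DESeq2 called 0, with 0 at an unadjusted p under 0.05 in edgeR. Each gene call given here was lost without EIC 1, EIC 3, 16IC 1 or 16IC 2 (edgeR adjusted p = 0.0845 to 0.197). Those of Tapbpl, Ikbke, Ifi203 and Ptges were also lost without EIC 2 (0.0536 to 0.0730). With no filter on low counts those of Tapbpl and Ikbke were lost (0.0735 and 0.0719), and with the robust fit that of Tapbpl (0.0508).

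**Figure D2:**
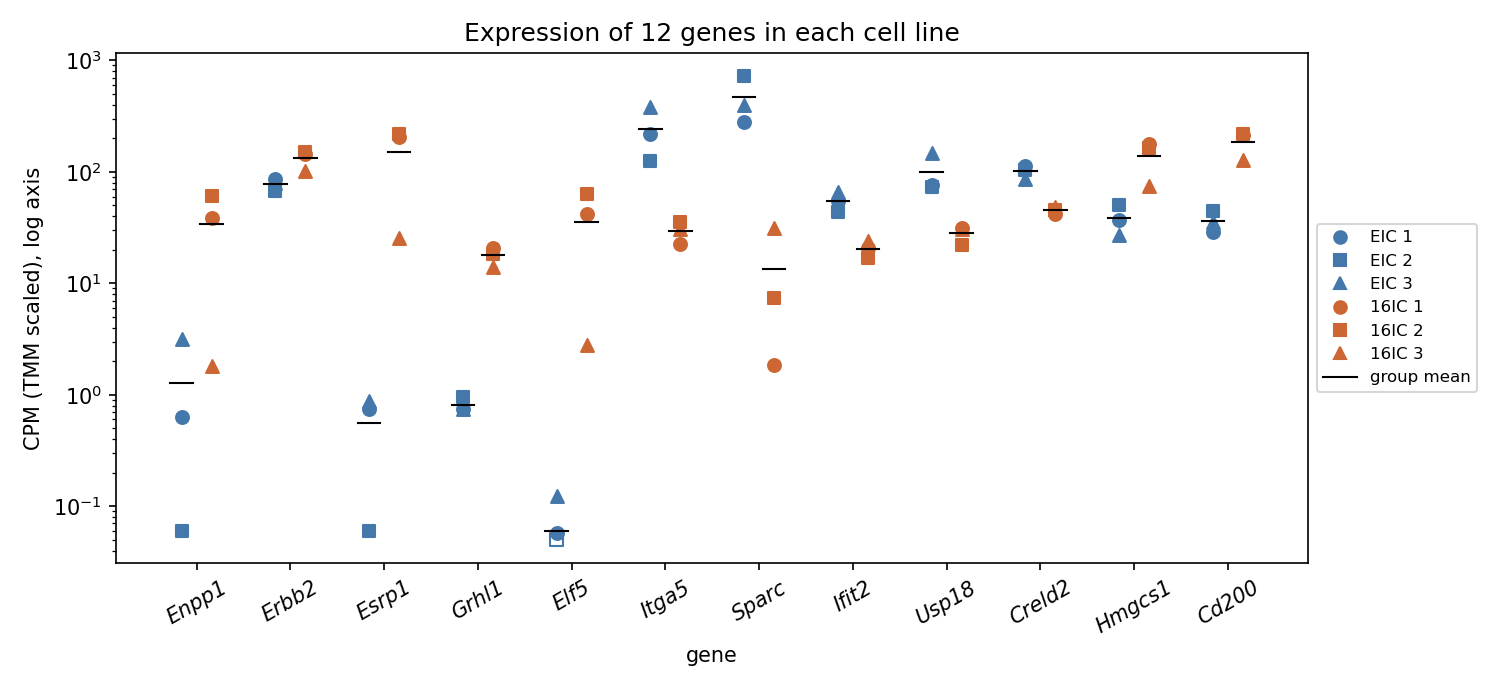
CPM of 12 named genes in each line on a log axis, with EIC in blue, 16IC in orange, 1 symbol per line, bars at the group means, and an open symbol for a value of 0, drawn at 0.05 CPM. Enpp1 was high in 16IC 1 (38.9 CPM) and 16IC 2 (61.1 CPM) and at 1.82 CPM in 16IC 3, while the groups of Ifit2, Creld2 and Cd200 did not overlap.

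Among the cell-type lists, camera called the luminal, mesenchymal and adipocyte markers with its preset correlation, and not the basal, fibroblast or endothelial ones. Of 32 tested luminal markers edgeR called 6 higher and 1 lower, and adjusted over the list alone 16 higher and 2 lower. Their median log2 fold change was 2.46, and camera called the list (adjusted p = 8.11e-05), though not with an estimated correlation (adjusted p = 0.567). Fry also called it (adjusted p = 0.0430). The epithelial regulator Grhl1 rose from 0.817 ± 0.126 CPM to 17.8 ± 3.41 CPM (log2 fold change 4.43, SE 0.33, edgeR adjusted p = 0.0181). The splicing factor gene Esrp2 rose from a mean of 1.49 CPM to 78.1 ± 54.2 CPM, and Ltf, which encodes the milk protein lactoferrin, from 1.37 CPM to 51.0 ± 16.5 CPM. The luminal level of 16IC 3 was 0.72, against 1.82 and 1.90 in the other 16IC lines and -2.12 to -0.44 in EIC. Mesenchymal markers were lower in 16IC, with a median of -1.59 over 33 members and a camera adjusted p of 0.0200, which became 0.475 with an estimated correlation and 0.0802 without EIC 2. Fry called this list too (adjusted p = 0.0413). Among them edgeR called the fibronectin receptor gene Itga5, which fell from 242 ± 129 CPM to 29.6 ± 6.69 CPM (edgeR adjusted p = 0.0390), and adjusted over the list alone 1 member was higher and 5 lower. The matrix gene Sparc had 468 ± 227 CPM in EIC and 13.4 ± 15.5 CPM in 16IC, and the regulator gene Twist1 had 92.5 ± 18.3 and 10.3 ± 8.23 CPM, without passing the edgeR test (adjusted p = 0.0679 and 0.0540). Of 13 fibroblast markers edgeR called Fbln1, which fell from 118 ± 54.2 CPM to 0.929 CPM and was also the 1 call adjusted over the list alone (camera adjusted p = 0.219, and 0.0303 with no filter on low counts, where the list was called lower). The fibroblast level was 2.49 in 16IC 3, above the EIC lines (-0.03 to 1.11), and -2.00 and -2.17 in the other 16IC lines. Col1a1 and Postn had positive log2 fold changes of 1.84 and 3.05 without passing the edgeR test (adjusted p = 0.131 and 0.194). Of 11 basal markers edgeR and voom called 0, with 4 at an unadjusted p under 0.05 in edgeR and 3 adjusted over the list alone, and DESeq2 called 3 (camera adjusted p = 0.520). Of 5 endothelial markers edgeR and voom called 0, with 2 at an unadjusted p under 0.05 in edgeR and 1 adjusted over the list alone, and DESeq2 called 1 (camera adjusted p = 0.450). Of 6 adipocyte markers edgeR and voom called 0, with 3 at an unadjusted p under 0.05 in edgeR and 2 adjusted over the list alone, and DESeq2 called 3, while camera called the list lower (median -2.66, adjusted p = 0.0291). That call was lost with an estimated correlation (adjusted p = 0.567) and without 16IC 1, 16IC 2 or 16IC 3 (adjusted p = 0.0913, 0.0705 and 0.0733), and 16IC 3 lay at -0.11, above EIC 2 at -0.46. Of 4 tested leukocyte markers the mannose receptor gene Mrc1 was called, at 2.13 ± 0.647 CPM in EIC and 0 counts in 16IC, at least 34.3-fold lower, and adjusted over the list alone 2 were. Xist, from the sex-linked list, rose from 571 ± 85.7 CPM to 2330 ± 764 CPM (edgeR adjusted p = 0.0423). Each gene call given here was lost without EIC 1, EIC 3, 16IC 1 or 16IC 2 (edgeR adjusted p = 0.0845 to 0.172), and those of Esrp2, Mrc1 and Xist also without EIC 2 (0.0638 to 0.0815). The call of Esrp2 was also lost in limma-voom (0.112).

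**Figure D3:**
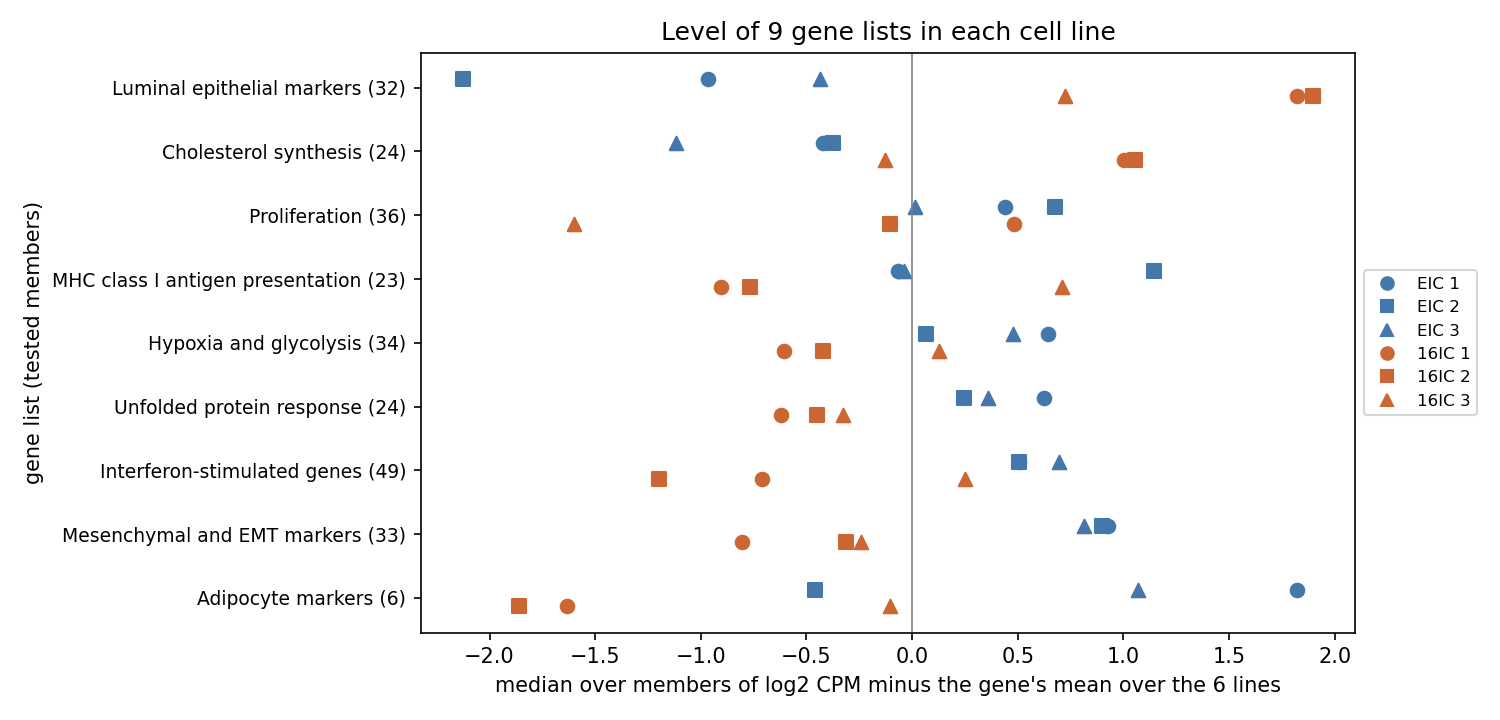
Level of the 9 lists that camera called with its preset correlation, as the median over members of log2 CPM centred per gene, with EIC in blue, 16IC in orange and 1 symbol per line. The line 16IC 3 stood at 0.25 for interferon-stimulated genes, between the other 16IC lines (-0.71 and -1.20) and the EIC lines (0.51 to 0.69).

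Of the metabolic, stress and growth lists, camera called 4 with its preset correlation. All 24 tested genes of cholesterol synthesis had a positive log2 fold change (median 1.36), and camera called the list (adjusted p = 1.66e-08) but not with an estimated correlation (adjusted p = 0.646). The edgeR test called 0 of them over all genes, with 18 at an unadjusted p under 0.05, and 16 adjusted over the list alone, while voom called 0 and DESeq2 13. The cholesterol level of 16IC 3 was -0.13, near EIC 1 and EIC 2 at -0.42 and -0.38 and far from 16IC 1 and 16IC 2 at 1.0 and 1.1, with EIC 3 at -1.12. Hmgcs1, which makes the precursor of mevalonate, had 38.3 ± 11.8 CPM in EIC and 139 ± 56.5 CPM in 16IC (edgeR adjusted p = 0.0700), and the farnesyl diphosphate synthase gene Fdps had 1.65 and 9.94 CPM (adjusted p = 0.0662). The unfolded protein response list was lower in 16IC, with a median of -0.89 over 24 members and a camera adjusted p of 2.68e-07, which became 0.475 with an estimated correlation. Fry called it as well (adjusted p = 0.0413). Of these edgeR called 1, the endoplasmic reticulum chaperone-like gene Creld2, and 12 adjusted over the list alone, all lower. Creld2 fell from 101 ± 13.4 CPM to 45.2 ± 3.24 CPM (edgeR adjusted p = 0.0390), a call lost without any line but 16IC 3 (adjusted p = 0.0609 to 0.175). Dnajc3 and Hyou1 had log2 fold changes of -1.45 and -1.07 without passing the edgeR test (adjusted p = 0.0592 and 0.0652), and Dnajc3 lies on chromosome 14. Of 34 hypoxia and glycolysis genes edgeR and voom called 0, with 10 at an unadjusted p under 0.05 in edgeR and 0 adjusted over the list alone, and DESeq2 called 6. Camera called the list lower (median -0.68, adjusted p = 0.000150), though not with an estimated correlation (adjusted p = 0.646). The hypoxia level of 16IC 3 was 0.13, above EIC 2 at 0.07 and far from 16IC 1 and 16IC 2 at -0.61 and -0.42. The lactate dehydrogenase gene Ldha had a log2 fold change of -1.21 (edgeR adjusted p = 0.0748), and Ero1l, which lies on chromosome 14, one of -1.62 (adjusted p = 0.0740). All 36 proliferation genes had a negative log2 fold change (median -0.52), and camera called the list (adjusted p = 0.000324), though not with an estimated correlation (adjusted p = 0.676) nor without 16IC 3 (adjusted p = 0.187). No proliferation gene was called by edgeR (0, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone), voom (0) or DESeq2 (0), and Cdc20 had a log2 fold change of -1.12 (edgeR adjusted p = 0.210). The proliferation level was -1.60 in 16IC 3, 0.48 and -0.11 in the other 16IC lines and 0.01 to 0.68 in EIC. Of 53 oxidative phosphorylation genes edgeR, voom and DESeq2 called 0, with 3 at an unadjusted p under 0.05 in edgeR and 0 adjusted over the list alone (median -0.10, camera adjusted p = 0.311).

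Camera called none of the 6 signalling lists as sets, and edgeR called 0 to 3 members of each. Of 15 ERBB receptors and ligands edgeR called 1, and 4 adjusted over the list alone (camera adjusted p = 0.390). That gene, the EGFR and ERBB2 inhibitor Errfi1, fell from 409 ± 72.7 CPM to 152 ± 28.3 CPM (log2 fold change -1.43, SE 0.23, edgeR adjusted p = 0.0432). Egfr had a log2 fold change of 2.87 without passing the edgeR test (adjusted p = 0.0621). Of 29 MAPK output genes edgeR called the AP-1 gene Jun, and adjusted over the list alone 2 higher and 2 lower (camera adjusted p = 0.311). Jun fell from 172 ± 25.5 CPM to 68.6 ± 10.0 CPM (edgeR adjusted p = 0.0390). Of 30 PI3K-AKT genes edgeR and voom called 0, with 8 at an unadjusted p under 0.05 in edgeR and 2 adjusted over the list alone, and DESeq2 called 3 (camera adjusted p = 0.221). Of 20 TGF-beta targets edgeR called 3, and 5 adjusted over the list alone (camera adjusted p = 0.197). Ltbp2, which encodes a matrix protein of the latent TGF-beta binding family, rose from 2.94 ± 1.01 CPM to 291 ± 200.2 CPM. Smad7, an inhibitor of the pathway, rose from 36.8 ± 1.86 CPM to 128 ± 35.6 CPM, and Bmp4, which lies on chromosome 14, fell from 22.2 ± 15.9 CPM to a mean of 0.644 CPM (edgeR adjusted p = 0.0369 and 0.0480). Of 18 Wnt genes edgeR called 2, also adjusted over the list alone (camera adjusted p = 0.311). Both rose, the Dishevelled-binding inhibitor gene Nkd2 from 1.17 to 116 CPM and the ligand gene Wnt5b from 0.387 to 31.5 CPM. Of 24 p53 targets edgeR called the receptor gene Eda2r, also the 1 call adjusted over the list alone, which fell from 45.3 ± 15.2 CPM to 1.09 CPM (edgeR adjusted p = 0.0372). The p53 list had a median of 0.10 and a mean of -0.30, with the sign of the test (camera adjusted p = 0.964). Each of these gene calls was lost without EIC 1, EIC 3 or 16IC 2 (edgeR adjusted p = 0.104 to 0.174), and all but that of Ltbp2 without 16IC 1 (0.0845 to 0.170). Those of Errfi1, Smad7, Bmp4 and Wnt5b were also lost without EIC 2 (0.0580 to 0.0838). That of Errfi1 was lost with no filter on low counts (0.0560), and those of Bmp4 and Wnt5b with the robust fit (0.0508 and 0.0511) and in limma-voom (0.0850 and 0.0903).

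Genes lower in 16IC were crowded on chromosome 14, a feature singled out after the values were seen. Of its 436 tested genes edgeR called 38 lower (8.72%) and 5 higher, against 126 of 13262 (0.950%) lower on the other chromosomes. Among genes whose group means sum to at least 10 CPM, the median log2 fold change was -0.95 from 0 to 40 Mb (107 genes) and -0.99 from 80 Mb on (43 genes), with 93.5% and 95.3% negative. From 40 to 70 Mb it was -0.44 and from 70 to 80 Mb -0.65. Per line, the median of centred log2 CPM from 0 to 40 Mb was 0.50, 0.46 and 0.48 in EIC 1 to 3 and -0.43, -0.42 and -0.55 in 16IC 1 to 3. From 40 to 70 Mb EIC 2 stood apart, at 0.87 against -0.14 in EIC 1, -0.18 in EIC 3 and -0.27 to -0.06 in 16IC. The other autosomes had medians of -0.25 to 0.26.

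**Figure D4:**
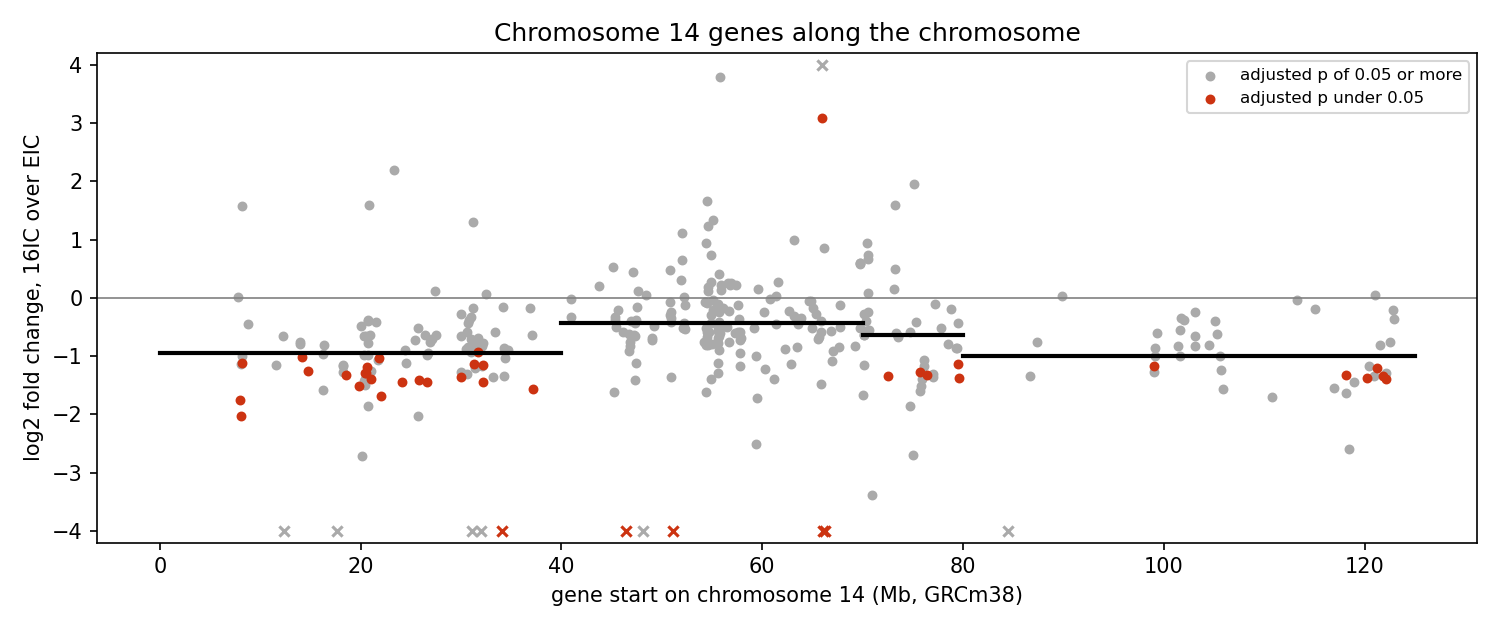
Log2 fold change of 16IC over EIC against gene start on chromosome 14 in Mb, for genes whose group means sum to at least 10 CPM, with genes called by edgeR in red and crosses for values beyond -4 or 4, drawn at that limit. Black bars mark segment medians, which were -0.95 from 0 to 40 Mb, -0.44 from 40 to 70 Mb, -0.65 from 70 to 80 Mb and -0.99 beyond.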

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

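Averaging 16IC 1 and 16IC 2 was the 1 alternative chosen only after the results were seen. The edgeR test called 335 genes with all 6 lines and 0 to 1913 when 1 line was left out. It called 0 without EIC 1, EIC 3 or 16IC 2, with 2251 to 2627 genes at an unadjusted p under 0.05, and 1913 without 16IC 3, among them all 335, and the cause was not tested. Averaging gave 0 in edgeR, with 2257 at an unadjusted p under 0.05, where 1 sample fewer entered the fit. The count was 223 with no filter on low counts, where 23449 genes were tested. DESeq2 called 2032, including all 335. On simulated counts 33.8% of its calls were false against 5.44% for edgeR. Those counts were drawn with edgeR's dispersions and 200 changed genes, so these shares do not give the share of false calls among the 2032. By construction, stricter or looser tests moved the count as well, to 44 against a fold of 1.5, 0 at an adjusted p under 0.01, where the smallest was 0.0143 and voom and DESeq2 were run at 0.05 only, and 1184 under 0.1. DESeq2 size factors (333), upper-quartile factors (343), the 1 CPM filter (367), the robust fit (307) and limma-voom (287) stayed within 1.5 times the count. Of 84 genes followed, edgeR called 48, and DESeq2 gave an adjusted p for 82. Under the other scalings, filters, sets of lines and tools 0 reversed. A change of sign was counted as a reversal only where the main fit or the alternative called the gene. Of the 48 calls limma-voom kept 33, the robust fit 43, no filter on low counts 44, upper-quartile factors 47 and the other scalings, filters and tools all 48, and all 48 were lost on averaging. Single genes were not followed through the 1.5-fold test or the other thresholds. Enpp1 kept its direction throughout, with a log2 fold change of 3.98 to 6.57 when 1 line was left out. It was called without 16IC 3 (5.28, adjusted p = 0.0471) and by DESeq2 (4.69, adjusted p = 0.00388), and its adjusted p reached 0.342 elsewhere. Erbb2 ranged over 0.66 to 0.91 when 1 line was left out and was called without 16IC 3 (0.91, adjusted p = 0.0259), with up to 0.305 elsewhere. For both genes the cause was not tested. Camera called 9 lists with its preset correlation, 7 to 9 when 1 line was left out, 7 with the averaged sample and 10 with no filter on low counts. The lists gained were fibroblast markers with no filter (adjusted p = 0.0303) and chemokines and cytokines without EIC 2 (adjusted p = 0.0456). It called 0 with an estimated correlation, where fry called 3, the luminal, mesenchymal and unfolded protein response lists. Interferon-stimulated genes were called under every scaling, filter and set of lines tried, but not with an estimated correlation (adjusted p = 0.646) or by fry (adjusted p = 0.175), both of which take the correlation between members from these samples. The mean distance within groups stayed at 0.0460 to 0.0824. The pseudocount, the filter on normalised values and the table of the authors' values alone were not run as alternatives, since they were meant for a file without counts. At 15621563 to 17468498 counts per library a floor of 3 counts over a group lies at 0.0597 CPM in EIC and 0.0620 CPM in 16IC, which is the bound used where all 3 lines of a group had 0 counts.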

Other observations

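The tests given here were chosen only after the result was seen, except the splits of the lines. Genes high in a single line, and the genes named for them, were also chosen after the values were seen. At 10 CPM or more and 4-fold or more above every other line there were 101 genes in 16IC 3, 91 in EIC 2, 11 in EIC 3, 2 in 16IC 1, 1 in EIC 1 and 0 in 16IC 2. A line closely matched by another, as 16IC 1 by 16IC 2 and EIC 1 by EIC 3, has few such genes by construction. Ctsd, which encodes a lysosomal protease, reached 8118 CPM in 16IC 3 and at most 1595 CPM in another line. Peg10, an imprinted gene, reached 596 CPM in EIC 2 and at most 17.3 CPM elsewhere. The epithelial adhesion gene Epcam had 1160, 1345 and 51.1 CPM in 16IC 1 to 3 and at most 3.79 CPM in EIC. The mesenchymal genes Vim and Zeb1 had 2099 and 45.7 CPM in 16IC 3, near the 2684 to 4398 and 38.4 to 57.8 CPM of the EIC lines, and at most 182 and 2.33 CPM in the other 16IC lines. The fibroblast list was also highest in 16IC 3, at 2.49 against at most 1.11 in another line, with Col1a1 and Col1a2 together at 4.99 CPM there. EIC 2 is the line titled with NT in place of a number.

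Of the 10 splits of the 6 lines into 3 and 3, the real one called 335 genes and the highest other 0, so that 1 split gave as many. For lists the real split called 9 and the other splits 3 to 10, and 4 splits gave as many, the real one included. The number of lists called therefore does not set the real split apart. With 10 splits a share under 0.05 cannot be reached.

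Luminal genes were high in 16IC 1 and 16IC 2, low in EIC and between in 16IC 3, and a plain mixture of the other lines' cells as the source of 16IC 3 was argued against by the 101 genes at least 4-fold above every other line, since a mixture holds no level above its parts. Admixed cells like 16IC 1 and 16IC 2 as the whole would need 1 share for all genes. Over 45 genes at 20 CPM or more in both of those lines and under 1 CPM in EIC, the ratio of 16IC 3 to them was taken. Its 75th percentile was 5.29 times its 25th (bootstrap interval 2.72 to 11.3). The interval holds the bound of 4 used first, under which the test was undecided. It lies wholly above a bound of 2 that replaced it after these values were seen, when whole and part were also split. No conclusion is therefore drawn on the whole. As a part such cells stayed open as well, because the 25th percentile was 1.65% (interval 1.20 to 2.10%), a level at which a small share of them and weak expression in the line's own cells cannot be told apart. Fibroblasts among the EIC cells, whose fixed list has 22 genes, 13 of them tested and 0 in another list, would bring type I collagen, yet Col1a1 and Col1a2 together reached at most 0.684% of Sparc (4.93 against 722 CPM in EIC 2). This covers only fibroblasts that make type I collagen. Of the 13 tested members 8 were lower in 16IC, among them Fbln1 (118 CPM in EIC, 0.929 in 16IC) and Pdgfra (63.2 and 7.88 CPM), and 5 were higher. A difference in cell state between lines, as a biological explanation, may remain for the 16IC lines and was not tested.

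Enpp1 was high in 16IC 1 and 16IC 2 alone. Extra copies of the full stretch within 1 Mb were argued against as the whole cause. Its 9 tested genes had a median log2 fold change that was 2.47% of that of Enpp1 (bootstrap interval -3.21 to 12.5%). The interval takes linked genes as independent, and this median cannot exclude extra copies of a shorter stretch. An earlier test of 16IC 1 and 16IC 2 against the other 4 lines was undecided and was replaced, as it grouped lines by the outcome. As a part of the cause extra copies might remain, since the median was 0.12 with an interval of -0.15 to 0.59, which is too wide to decide. The neighbour Arg1 had the same pattern, with 52.5, 42.5 and 1.10 CPM in 16IC 1 to 3 and at most 0.241 CPM in EIC (edgeR adjusted p = 0.0676). Ctgf, another neighbour, had a log2 fold change of 2.10 (edgeR adjusted p = 0.129), with 693, 1166 and 334 CPM in 16IC 1 to 3 and at most 301 CPM in EIC. The other neighbours lay between -0.19 for Akap7 and 0.59 for Med23. At 10 CPM or more, 88 genes were at least 8-fold higher in both of these lines than in the other 4, so the pattern is shared by many genes, and no biological explanation was tested.

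Chromosome 14 genes were lower in 16IC at both ends of the chromosome. A scaling factor per library moves all chromosomes alike, so it cannot set a single chromosome apart. The other autosome farthest from 0 had a median of 0.26, but TMM centres most genes near 0, so this value was no separate test. Fewer copies of these ends in 16IC, or more in EIC, might be a candidate explanation, and the medians were -0.88 (interval -0.99 to -0.78) for the 75 less expressed genes and -1.04 (interval -1.17 to -0.87) for the 75 more expressed ones. These genes lie in the segments picked for their low medians, so the values decide nothing, and a copy difference and a change in regulation along the chromosome cannot be told apart. The data used here hold no DNA measurement of these samples, and a link to the transgenes was not tested.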
